A study of Mus musculus with 6 samples.

How the data were processed

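RNA from femur, of 6 mice by the design text, 3 knockout-labelled and 3 corn oil controls, was sequenced. Per the labels' protocols, the libraries were poly(A)-selected, stranded and read as 150-base pairs on a NovaSeq X Plus. Groups were taken from the treatment label of each sample, and replicate numbers from the titles. The deposited tables hold values per gene and per transcript, in 2 units. FPKM values were computed by the authors (fragments per kilobase of transcript, scaled to sequencing depth), and their column totals differ between libraries. The deposited estimated counts are whole numbers, and the gene counts are sums over the transcripts of a gene. Each deposited transcript count equalled its FPKM times the transcript length and a constant per library, rounded up, within 1 count for 100% of values above 0, so these are expected counts made from coverage rather than tallies of reads. The submitters' processing notes name fastp, HISAT2, StringTie and RSEM, without versions or roles, and the genome build GRCm39. The filters, strand setting and annotation release used are not given in the sources used here. Coordinates are those of the tables, and a reference genome of another build was not used for them. Reference name tables served only to match older gene symbols.

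In single-exon genes with 1 transcript longer than 1500 bases, 43.8% to 49.2% of counts from 1 to 12 were exactly 4, 8 or 12. A read pair was therefore taken to add about 4 counts, which puts the depth at 16.4 to 18.4 M read pairs per library. The floor for a gene with 0 counts was set at 3 read pairs, or 12 counts. Floors cover counting error only, since PCR copies are not independent molecules.

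The planned main test was limma on log2(FPKM + 1), to be replaced by a count test where the table held counts. Because the tables held expected counts, edgeR 4.0.16 in R 4.3.3 was used, with counts rounded to whole numbers, filterByExpr, TMM scaling, the quasi-likelihood F test (two-sided) and Benjamini-Hochberg adjustment at 0.05. Limma 3.58.1 on log2(FPKM + 1), for genes at FPKM 1 or more in 3 libraries, became an alternative. Only the group entered the model, as all 6 libraries belong to the 2 groups compared. Of 34361 genes, 20388 passed the filter and held 99.96% of counts. The SE beside a log2 fold change comes from the spread of log2 CPM (prior count 2) between the replicates of each group. FPKM means are given as deposited and were not rescaled, so their ratio differs from the TMM-scaled fold change. Adjusted p-values from edgeR rest on a variance shared across genes, while an exact permutation test of 3 against 3 could not go below p = 0.1.

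Before the data were examined, 43 gene lists with 995 entries were fixed. Of these entries 979 matched a symbol in the table, 13 matched through a name table and 3 did not match. Lists with at least 5 tested genes (42) were tested with camera on log2 CPM with a preset correlation of 0.01, then with an estimated correlation, and with fry for movement in one direction. Camera with an estimated correlation rests on the residual degrees of freedom of 6 libraries. Its p-values therefore stay larger, and a call lost there need not come from correlated genes. The tendon and ligament list, for example, lost its call at an estimated correlation of -0.067, below the preset value. GO and KEGG terms given in the gene table were tested with the same camera call where 15 to 300 tested genes carried the term. Genes named in the text followed a rule fixed together with the lists. It took Fshr and Fgf21, the 12 largest and 12 smallest log2 fold changes among named genes past the threshold without overlap between groups and with a mean FPKM of at least 2, and up to 4 members of each described list by adjusted p. It also took the 6 most abundant genes past the threshold and 8 bone cell genes. Predicted genes, immunoglobulin and T-cell receptor segments, olfactory receptors and ribosomal pseudogenes were skipped. Not every list member that the rule took is printed, for brevity or because a gene is not reported here. Members of a list named outside this rule are said to be so in the text.

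The steps were tested on simulated counts for the knockout-labelled against control comparison. Counts were drawn from the means of the real genes, the library sizes and the trend of dispersion with abundance. Changed genes were drawn only among those above a minimum mean count, so recovery does not apply to rare genes. They were also a far smaller share than the 57.5% called in the real data, so scaling under that many changes was not tested. Of 200 changed genes among 19924, edgeR recovered 47 of 67 at 1.5-fold, 59 of 67 at 2-fold and 66 of 66 at 4-fold, and called 6 of 19724 unchanged genes. Limma recovered 171 of the 200 on the log2 CPM of the same simulation. Camera called the 1 raised list and 0 of 40 unchanged lists. Those lists were random genes simulated independently, so this does not cover lists of correlated genes. The mitochondrially encoded list, for example, had an estimated correlation of 0.47.

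Alternatives covered the pseudocount, the filter on low values, the scaling between libraries (median-of-ratios, TPM, quantile, totals without haemoglobin, mitochondrial and immunoglobulin genes, and library totals alone), the variance prior, library weights, the replicate number as a block, each library left out in turn, the level of the skeletal muscle list as a covariate, DESeq2 1.42.0 and other thresholds. The closing section gives their effect. No column of sample values was left unused.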

Results

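The data set held 6 poly(A)-selected RNA-seq libraries from mouse femur, 3 from animals given tamoxifen to induce a gene knockout and 3 from control animals injected with corn oil. The design text describes the samples as 3 mice per group. It names Fshr, the receptor for follicle-stimulating hormone, as the gene knocked out, and the series title concerns the inhibition of this hormone in osteocytes of ovariectomized mice. The treatment label of the samples names FGF21 instead, so the libraries are called knockout-labelled throughout. Only the knockout-labelled animals received tamoxifen, so the drug and the knockout were not separated by the design. The labels do not say whether these femora came from ovariectomized or fractured animals. Estimated counts per library summed to 65.8 to 73.5 M, and 24534 to 25977 of the 34361 genes had a count above 0. These counts overstate the depth, because low counts piled up at multiples of 4, which puts the depth at 16.4 to 18.4 M read pairs per library if a pair adds 4 counts.

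The targeted genes were examined first, as a check of the labels. Fshr (ENSMUSG00000032937, chromosome 17, 89292380 to 89508103, minus strand, GRCm39) had 0 counts in all 6 libraries, in both the gene and the transcript table. Fgf21 (ENSMUSG00000030827, chromosome 7, 45263310 to 45264914, minus strand), which encodes a circulating metabolic hormone, also had 0 counts in all 6 libraries. The limit that a count of 0 allows, 3 read pairs or 12 counts, was 0.163 to 0.182 CPM (counts scaled to library depth) per library and covers counting error only. Neither gene was detectable at this depth in either group, so these libraries could not show which gene was deleted or whether deletion took place.

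The comparison of knockout-labelled with control femora asked which genes differed between the groups. The groups differed in the balance between skeletal muscle and bone transcripts. The 28 genes of a skeletal muscle list made up 13% ± 0.0403 (SD, n = 3) of all counts in the knockout-labelled libraries and 2.81% ± 0.020 (SD, n = 3) in the controls. The 28 genes of an osteoblast and bone matrix list went the other way, at 2.30% ± 0.0116 and 11.3% ± 0.0573 of counts (SD, n = 3 each). The 23 genes of an osteoclast list, which marks the bone-resorbing cells, held 0.248% ± 0.00149 and 1.32% ± 0.00300 of counts in the same order (SD, n = 3 each).

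**Figure D1:**
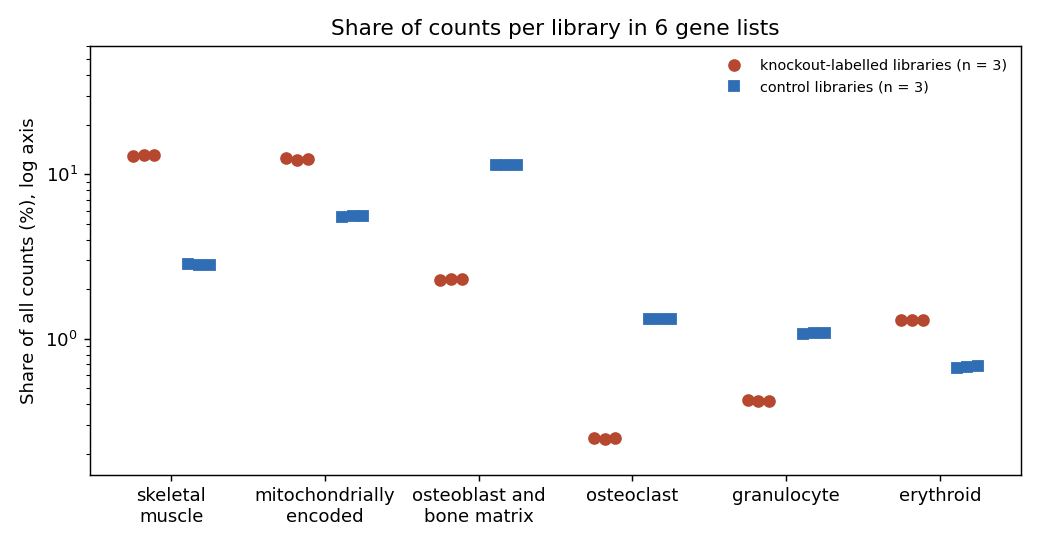
Share of all counts, in percent on a log axis, taken by 6 gene lists in each of the 3 knockout-labelled (circles) and 3 control (squares) libraries. The skeletal muscle list lay at 12.9% to 13% in the knockout-labelled libraries and at 2.80% to 2.84% in the controls, and the osteoblast list at 2.29% to 2.31% and 11.3% to 11.4%.

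Across all genes, 5860 of the 20388 tested were higher and 5872 were lower in the knockout-labelled libraries (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), or 57.5% of those tested. Of these, 2471 were at least 2-fold higher and 1656 at least 2-fold lower, while 807 and 471 passed 4-fold. The 3 libraries of one group lay entirely on one side of the other group for 13138 genes (64.4%), where chance gives 10%. The division between higher and lower genes depended on the scaling. The limma settings given here also differed in the test and in the genes tested (13778). Median-of-ratios scaling gave 5906 higher and 5827 lower, and quantile normalization in limma 4534 and 5542. Library totals alone gave 3379 higher and 10339 lower, and TPM values in limma, which tested 13778 genes, gave 1832 and 10738. Limma on log2(FPKM + 1) gave 2822 and 8780. Relative to the TMM-scaled values, library totals shifted the median gene by -0.42 and TPM by -0.73 on the log2 scale, so all fold changes given here are relative to the median gene. With the level of the skeletal muscle list as a covariate, which shared 99.9963% of its variance with the group, 0 genes passed by edgeR (970 at an unadjusted p under 0.05; DESeq2 was run only without the covariate).

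Genes of bone-forming cells fell together. In the osteoblast and bone matrix list 27 of 28 genes were lower and none was higher, with a median log2 fold change of -1.61 (camera adjusted p = 8.3e-20, and adjusted p = 0.0084 with an estimated correlation). Adjusted over the list alone, 27 genes passed. Col1a1 and Col1a2, the chains of type I collagen, fell from 5537 ± 64.4 to 1074 ± 12.4 FPKM and from 3065 to 586 FPKM, with log2 fold changes of -1.94 (SE 0.0089) and -1.96 (SE 0.0073). Sparc (osteonectin) changed by -1.79 and Spp1 (osteopontin) by -2.27 on the log2 scale. Bglap, the gene of osteocalcin, went from 2524 ± 73.3 to 475 ± 8.31 FPKM (SD, n = 3 each), a log2 fold change of -1.98 that is uncertain because Bglap2 and Bglap3 are near-identical copies. The muscle transcripts described above moved with this group of genes, in the opposite direction.

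Osteocyte genes, which mark the cells embedded in bone, went in both directions. Of 20 tested members 4 were higher, 10 were lower and 6 did not pass, 14 passed adjusted over the list alone, and the list missed the threshold against other genes (median log2 fold change -0.29, camera adjusted p = 0.077, and adjusted p = 0.19 with an estimated correlation). It passed in the lower direction under 7 of 22 alternatives, the muscle covariate not counted, at camera adjusted p from 0.0062 with quantile normalization to 0.049 by limma on log2(FPKM + 0.1), and also by limma on log2(FPKM + 1), with library weights, TPM, library totals and no filter. By fry, which tests whether a list's genes moved on balance one way without comparing them with other genes, its adjusted p was 6.3e-07. That test called 40 of the 42 lists, so its call does not set the osteocyte list apart. Sost, which encodes the Wnt inhibitor sclerostin, was higher, at 558 ± 5.04 against 387 ± 4.57 FPKM (SD, n = 3 each; log2 fold change 0.95, SE 0.010). The size of this rise depends on the scaling, since library totals and TPM shifted the median gene by -0.42 and -0.73. Dmp1, a mineralization protein of osteocytes, was lower, at 173 ± 2.04 against 379 ± 1.34 FPKM (log2 fold change -0.70, SE 0.013). Gja1, which encodes the gap junction protein connexin 43, and the protease gene Mmp14 fell by 1.57 and 1.58 on the log2 scale.

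Genes of osteoclasts fell as well. In the osteoclast list 19 of 23 genes were lower, 2 were higher and 2 did not pass, 21 passed adjusted over the list alone, and the median log2 fold change was -1.57 (camera adjusted p = 1.1e-09, and adjusted p = 0.015 with an estimated correlation). Ctsk, the collagen-degrading cathepsin of osteoclasts, went from 2121 ± 2.35 to 241 ± 3.02 FPKM (SD, n = 3 each; log2 fold change -2.71, SE 0.013). Acp5, which encodes tartrate-resistant acid phosphatase, changed by -2.20, Mmp9 by -2.46 and the proton pump subunit gene Atp6v0d2 by -2.32 on the log2 scale. The 2 higher members were Fos (1.85) and Car2 (0.96), named after their values were seen. Fos is also fixed in a list of stress and immediate early genes, so its rise need not come from osteoclasts. Among osteoclast regulators 10 of 15 tested genes were lower and 2 higher, 12 passed adjusted over the list alone, and the median was -0.62 (camera adjusted p = 0.015, lost at adjusted p = 0.11 with an estimated correlation and under 5 of the 22 alternatives, at 0.089 to 0.38). Tnfsf11, which encodes the osteoclast-inducing ligand RANKL, fell from 13.7 ± 1.13 to 1.61 ± 0.112 FPKM (SD, n = 3 each; log2 fold change -2.66, SE 0.092). Tnfrsf11b, which encodes its decoy receptor, was lower by less (log2 fold change -0.36, SE 0.038), and Csf1 changed by -1.19.

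**Figure D2:**
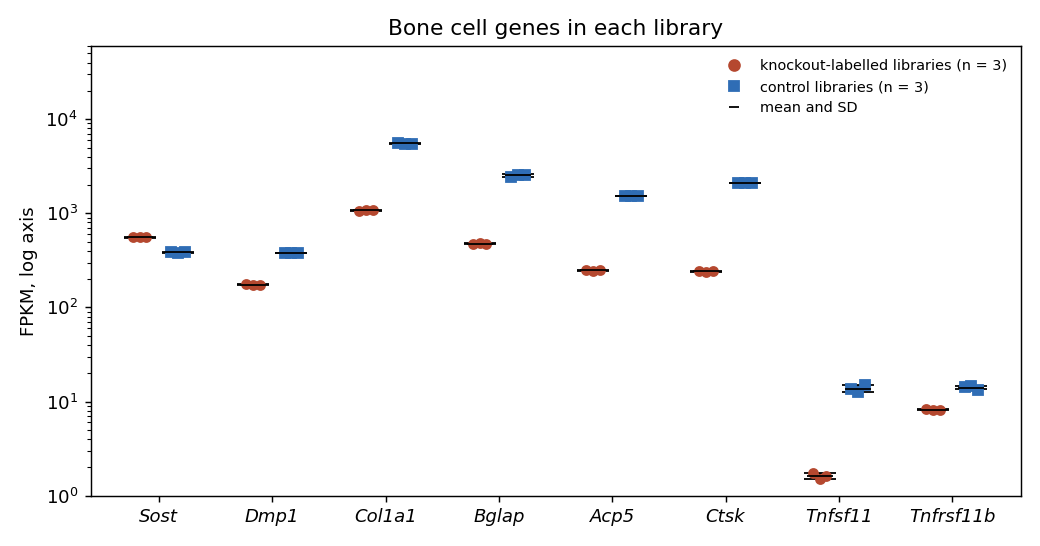
FPKM on a log axis of 8 bone cell genes in each library, with circles for the 3 knockout-labelled and squares for the 3 control libraries and black marks for the mean and SD of each group. Sost was the only one of the 8 with a higher mean in the knockout-labelled libraries (558 against 387 FPKM).

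Matrix remodelling genes fell along with the bone genes, with 35 of 40 lower, 3 higher and a median log2 fold change of -1.07 (camera adjusted p = 8.3e-16, and adjusted p = 0.0084 with an estimated correlation). Adjusted over the list alone, 38 passed. Mmp13, a collagenase of bone and cartilage (ENSMUSG00000050578, chromosome 9, 7272514 to 7283331, plus strand), went from 1617 ± 17.1 to 70.5 ± 0.417 FPKM (SD, n = 3 each), a 17.1-fold decrease after TMM scaling (log2 fold change -4.09, SE 0.012). Lox, which crosslinks collagen, and Col6a3 changed by -1.98 and -1.92. In a list of Wnt pathway genes 23 of 40 were lower and 9 higher, 33 passed adjusted over the list alone, and the median was -0.41 (camera adjusted p = 0.015, lost at adjusted p = 0.13 with an estimated correlation and under 4 of the 22 alternatives, at 0.11 to 0.15). Its members Lrp4, a sclerostin receptor, Sfrp4 and Wif1 changed by -1.66, -1.85 and -1.19. In BMP and TGF-beta signalling 22 of 35 genes were lower and 8 higher, 30 passed adjusted over the list alone, and the median was -0.31 (camera adjusted p = 0.0069, lost at adjusted p = 0.074 with an estimated correlation). Bmp1 (-1.74), Tgfbr1 (-1.72) and Tgfbr2 (-1.02) were among those that fell. Mineral and phosphate handling genes, a list that shares members with the osteoblast and osteocyte lists, had 10 of 18 lower and 5 higher, 15 past the threshold adjusted over the list alone, and a median of -0.53 (camera adjusted p = 0.010, lost at adjusted p = 0.093 with an estimated correlation).

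All 28 skeletal muscle genes were higher, with a median log2 fold change of 2.69 (camera adjusted p = 2.4e-28, and adjusted p = 0.0084 with an estimated correlation), and 28 passed adjusted over the list alone. Acta1, skeletal muscle actin, rose from 3165 ± 58.2 to 12296 ± 52.5 FPKM (SD, n = 3 each; log2 fold change 2.38, SE 0.013). Myh4, the myosin heavy chain of the fastest fibres, Actn3, the creatine kinase gene Ckm and the calcium pump gene Atp2a1 rose by 3.65 (SE 0.017), 3.10, 2.92 and 2.76 on the log2 scale. Myh7 and Tnni1, 2 slow-fibre members named after their values were seen, rose by 1.23 and 1.04. Slow and fast members were not compared as sets. The 12 largest log2 fold changes under the rule for named genes included those of Actc1 (5.98, SE 0.10), Mybph (4.94), Lrrc14b (4.83), Rasd2 (4.63), Myh8 (4.48), Kcng4 (4.28), Mylk4 (4.09) and Prkag3 (3.97), beside 4 members of the adipocyte list.

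Respiratory chain genes rose beside the muscle genes. All 35 nuclear genes of the oxidative phosphorylation list were higher, with a median log2 fold change of 1.35 (camera adjusted p = 5.3e-23, and adjusted p = 0.011 with an estimated correlation). Atp5f1b rose by 1.39, Atp5f1a by 1.33, Uqcrc1 by 1.51 and Atp5f1c by 1.35 on the log2 scale, and 35 passed adjusted over the list alone. All 13 mitochondrially encoded genes were higher with a median of 1.58 (camera adjusted p = 8.3e-14, lost at adjusted p = 0.093 with an estimated correlation), and 13 passed adjusted over the list alone. They held 12.4% ± 0.169 of counts against 5.54% ± 0.0428 (SD, n = 3 each). Among the most abundant genes, mt-Co1 (1.56), mt-Cytb (1.58), mt-Nd1 (1.71) and mt-Atp6 (1.39) were higher on the log2 scale. The mt-Atp6 value and that of its nuclear copy Atp6-ps (1.39) are uncertain, since reads of near-identical copies can be split between them, and with quantile normalization both were lower, at -0.08 and -0.10. That scaling gives equal values to equal ranks and mt-Co1 ranked first in all 6 libraries, so it cannot show a change in mt-Co1 and compresses those of other top-ranked genes, with a list median of 0.16 (camera adjusted p = 0.033). Hypoxia, angiogenesis and glycolysis genes had 17 of 26 higher and 3 lower, 21 past the threshold adjusted over the list alone, and a median of 0.68 that turned to -0.08 with TPM (camera adjusted p = 2.0e-05, lost at adjusted p = 0.052 with an estimated correlation). Its leading members were the glycolytic genes Aldoa (2.49), Ldha (2.06), Pkm (1.61) and Pgk1 (1.40).

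Fat and tendon genes were higher too. In the adipocyte list 22 of 24 genes were higher and 1 was lower, 23 passed adjusted over the list alone, and the median log2 fold change was 1.69 (camera adjusted p = 2.4e-12, and adjusted p = 0.011 with an estimated correlation). Cfd (adipsin) rose from 10.4 ± 0.508 to 202 ± 2.17 FPKM (SD, n = 3 each; log2 fold change 4.70, SE 0.045). Plin1, which coats lipid droplets, rose by 4.30, Retn (resistin) by 4.23, Cidec by 4.03 and the desaturase gene Scd1 by 3.12. The lower member was Ucp1 (-1.61), whose call was lost without control replicate 2 (edgeR adjusted p = 0.052). Of 9 tendon and ligament genes 7 were higher and 2 lower, 9 passed adjusted over the list alone, and the median was 1.31 (camera adjusted p = 0.015, lost at adjusted p = 0.11 with an estimated correlation). Cilp, Cilp2 and Kera rose by 1.85, 2.71 and 3.07.

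Blood and marrow cell lists moved apart from one another. In the erythroid list 24 of 25 genes were higher and 1 was lower, 25 passed adjusted over the list alone, and the median was 1.41 (camera adjusted p = 7.9e-14, and adjusted p = 0.022 with an estimated correlation). Hba-a1 and Hba-a2, near-identical alpha globin genes and so uncertain singly, both rose by 1.47 and 1.48, and the membrane skeleton gene Ank1, which muscle also expresses, rose by 2.59. B cell genes had 18 of 25 higher and 1 lower, 19 past the threshold adjusted over the list alone, and a median of 0.93 (camera adjusted p = 7.4e-05, lost at adjusted p = 0.062 with an estimated correlation). Cd24a rose by 1.13. Granulocyte genes went down, with 25 of 26 lower, 26 past the threshold adjusted over the list alone, and a median of -0.92 (camera adjusted p = 1.7e-13, and adjusted p = 0.031 with an estimated correlation). Ngp, Ltf, S100a9 and Chil3, products of neutrophil granules and cytosol, changed by -1.11, -0.97, -0.89 and -0.97. Monocyte and macrophage genes had 18 of 24 lower and 2 higher, 20 past the threshold adjusted over the list alone, and a median of -0.54 (camera adjusted p = 0.00014, lost at adjusted p = 0.052 with an estimated correlation). Csf1r, which encodes the receptor for macrophage colony-stimulating factor, and Cd68 fell by 1.78 and 1.76, and osteoclasts express both.

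Mast cell protease genes were among the largest decreases that the rule for named genes took. Cma1 went from 34.1 ± 0.368 to 0.547 ± 0.192 FPKM (SD, n = 3 each; log2 fold change -5.52, SE 0.29). Mcpt4, Tpsb2 and Cpa3 changed by -5.42, -5.28 and -3.35. The mast cell, basophil and eosinophil list that holds them had 11 of 21 lower and 2 higher, 15 past the threshold adjusted over the list alone, and a median of only -0.35 (camera adjusted p = 0.0024, lost at adjusted p = 0.069 with an estimated correlation). The basophil protease genes Mcpt8 (0.69) and Prss34 (0.51), named after their values were seen, were its higher members. With library totals neither passed (edgeR adjusted p = 0.085 and 0.32), Prss34 did not pass by limma on log2(FPKM + 1) either (adjusted p = 0.17), and with TPM Mcpt8 was at -0.078 (limma adjusted p = 0.41) and Prss34 passed in the opposite direction at -0.26 (adjusted p = 0.0018). Other large decreases were those of the chemokine gene Ccl8 (-5.00), Sftpa1 (-4.57), Shisal1 (-4.03), Ccn5 (-3.75), the carbonic anhydrase gene Car12 (-3.81) and the thyroid hormone deiodinase gene Dio3 (-4.04) with its antisense neighbour Dio3os (-4.29). The granzyme gene Gzme was at 17.1 ± 2.43 FPKM (SD, n = 3) in the controls and at 0, 0 and 0.105 FPKM in the knockout-labelled libraries, and it has close paralogs, so its value is uncertain.

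**Figure D3:**
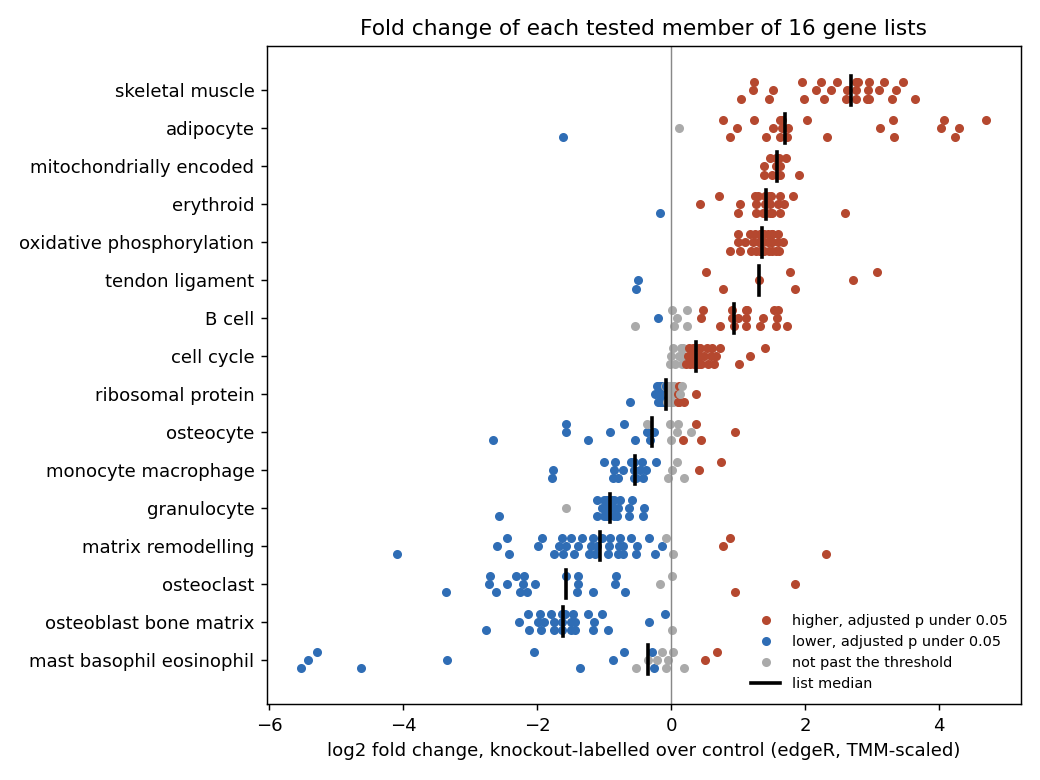
log2 fold change, knockout-labelled over control, of each tested member of 16 gene lists (edgeR, TMM-scaled), with red for higher, blue for lower and grey for not past the threshold, and a black bar at each list's median. The skeletal muscle median lay at 2.69 and the osteoblast median at -1.61, while the cell cycle median of 0.37 turned to -0.05 with library totals and -0.37 with TPM and the ribosomal protein median lay at -0.07.

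The lists tied to the targeted receptor and hormone did not pass the test against other genes. In FSH receptor and cyclic AMP signalling 10 of 28 tested genes were higher and 12 lower, 24 passed adjusted over the list alone, and the median of 0.08 turned to -0.34 with library totals, -0.26 by limma on log2(FPKM + 1) and -0.62 with TPM (camera adjusted p = 0.63). Adcy3 changed by -1.88 and Prkar2a by 1.62. In the FGF21 axis 5 of 10 tested genes were higher and 4 lower, 9 passed adjusted over the list alone, and the median of 0.70 turned to -0.19 with quantile normalization, -0.51 by limma on log2(FPKM + 1) and -0.91 with TPM (camera adjusted p = 0.99, in the downward direction). Cpt1b rose by 2.09, Fgfr3 and Fgfr2 fell by 1.99 and 1.33. In an oestrogen and sex steroid list 6 of 19 tested genes were higher and 8 lower, 14 passed adjusted over the list alone, and the median was -0.04 (camera adjusted p = 0.35). In a list for drug exposure, fixed because of the tamoxifen, 7 of 11 tested genes were higher and 1 lower, 8 passed adjusted over the list alone, and the median of 0.49 turned to -0.26 with TPM (camera adjusted p = 0.19). Of its members Nqo1 rose by 1.18 and Cyp1b1 fell by 1.15.

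In all, 22 of the 42 lists tested passed camera with a preset correlation of 0.01, 10 higher and 12 lower, and 9 passed with an estimated correlation. Those 9 were the skeletal muscle, oxidative phosphorylation, adipocyte, erythroid, cell cycle, osteoblast, osteoclast, matrix remodelling and granulocyte lists. With TPM values in limma 7 of the 22 lists no longer passed, at camera adjusted p of 0.95 for cell cycle, 0.38 for osteoclast regulators, 0.21 for interferon response, 0.15 for Wnt, 0.14 for inflammatory cytokines, 0.099 for immediate early genes and 0.052 for mast cells. By limma on log2(FPKM + 1) 5 no longer passed, at 0.068 for cell cycle, 0.17 for osteoclast regulators, 0.11 for interferon response, 0.11 for Wnt and 0.10 for immediate early genes, and the tendon list did not pass among genes at FPKM 5 or more (0.22). Within annotation terms 363 of 1895 passed, 205 higher and 158 lower, and 0 passed with an estimated correlation (smallest adjusted p = 0.14). Over so many terms that version could hardly call any. Even the term in front, at an unadjusted camera p of 2.6e-32 with the preset correlation, reached only 0.14 there. The terms in front were mitochondrial ATP synthesis among those higher (60 of 60 genes higher) and the lysosome among those lower (92 of 126 genes lower). In the transcript table, 8643 of 47621 tested transcripts passed, 4866 higher and 3777 lower, from 7159 genes, while DESeq2 called 14640 and limma on TPM 14150.

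The replicates of a group differed little. Correlations of log2(FPKM + 1) across genes, which are not independent replicates, were 0.9958 to 0.9962 within groups and 0.9570 to 0.9578 between them. The median variation coefficient of genes with a mean of at least 10 FPKM was 3.07% in the knockout-labelled and 2.90% in the control libraries. The median squared deviation of a pair was 1.52 to 1.61 times that of read-pair sampling within groups and 46.2 to 48.6 times between groups. This ratio takes read pairs as independent molecules and 4 counts per pair. PCR copies were not measured, so the excess within groups cannot be divided between them and differences between libraries. All 6 libraries entered as separate samples, as the labels give them, and the p-values measure the spread between these libraries only.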

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

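Library totals alone, counts divided by 4 and the separate counts of genes at least 2-fold higher or lower were added after the data were seen, and the other alternatives were chosen before. Except with the muscle covariate described last and the unadjusted p with a 2-fold change, under the settings with TMM or median-of-ratios scaling and no stricter filter on low values the counts of higher and lower genes stayed within 1.5 times 5860 and 5872, and DESeq2 called 11602 of the 11732 genes in the same direction. Genes higher numbered 2822 by limma on log2(FPKM + 1), 2819 with a pseudocount of 0.1, 2826 with library weights, 3223 among genes at FPKM 5 or more, 1832 with TPM, 3379 with library totals and 2574 at an unadjusted p under 0.05 with a 2-fold change. Genes lower numbered 8780, 8754 and 8784 in the first 3 of these settings, so that 24.3% of calls were higher by limma on log2(FPKM + 1), and 3278 at FPKM 5 or more, 10738 with TPM, 10339 with library totals and 1754 at an unadjusted p under 0.05 with a 2-fold change. Genes at least 2-fold higher numbered 740 by limma on log2(FPKM + 1), 997 with a pseudocount of 0.1, 741 with library weights, 1143 at FPKM 5 or more, 554 with TPM, 1476 with library totals and 1068 with quantile normalization. Genes at least 2-fold lower numbered 626 at FPKM 5 or more, 4025 with TPM, 3720 with library totals and 724 with quantile normalization. The FPKM 5 filter tests fewer genes, and TPM and totals shift all fold changes down. Lists past the threshold numbered 9 with an estimated correlation and 40 with fry. Transcripts past the threshold numbered 14150 with TPM and 14640 by DESeq2, for which the cause was not tested. Leaving out 1 library at a time gave 5536 to 5598 genes higher, 5359 to 5734 lower, 2397 to 2459 and 1539 to 1754 at least 2-fold higher and lower, 21 to 23 lists and 5990 to 6675 transcripts. Fshr and Fgf21 stayed at 0 counts, a limit of depth. With the replicate number as a block, 5673 genes were higher and 5671 lower, the 22 lists were called in both, and transcripts numbered 4483. Deviations of same-numbered libraries correlated at 0.005, 0.003 and -0.009, so the numbers do not pair the samples. With TPM the cell cycle list median was -0.37, Mcpt8 was at -0.078 and Prss34 at -0.26, and with quantile normalization, which sets equal ranks equal and so compresses top-ranked genes, mt-Atp6 and Atp6-ps were at -0.085 and -0.10. The level of the skeletal muscle list as a covariate shared 99.9963% of its variance with the group, so the group difference has almost no information left and its estimates scatter widely. It left 0 genes higher, 0 lower and 0 transcripts past the threshold by edgeR (970 genes and 1820 transcripts at an unadjusted p under 0.05), 0 genes at least 2-fold higher or lower, and 1 list. Of the 110 named genes, all past the threshold without the covariate, none passed with it, and 44 turned sign, with log2 values of 0.17 for Acp5, -2.27 for Ank1, 1.39 for Bglap, 0.70 for Bglap2, 72.55 for Bglap3, -0.23 for Car2, 32.01 for Ccl8, -2.58 for Cd24a, 12.66 for Cd68, 58.29 for Cdkn2a, -9.16 for Cidec, -32.86 for Cilp2, 5.17 for Col6a3, 11.95 for Cox6a1, 4.38 for Cpa3, 9.47 for Csf1, 1.32 for Csf1r, 0.22 for Ctsk, 2.17 for Cyp1b1, 48.59 for Dio3os, 2.36 for Dmp1, 6.50 for Fgfr3, -12.72 for Fosb, -14.38 for Kcng4, -0.65 for Ldha, 40.47 for Lif, 0.43 for Ltf, -19.89 for Mcpt8, -1.40 for Myh7, -15.91 for Myh8, 2.85 for Nfkbia, 1.99 for Ngp, -16.88 for Nqo1, -41.51 for Retn, 2.57 for S100a9, -0.87 for Scd1, 0.60 for Sfrp4, 18.48 for Shisal1, -0.99 for Sost, 1.01 for Tgfbr2, 5.16 for Tnfrsf11b, -6.47 for Tnni1, 99.63 for Ucp1 and -1.51 for Uqcrc1. Of the 22 lists, 10 turned direction by camera and were no longer past the threshold, with medians of -1.22 for BMP and TGF-beta signalling, 2.83 for granulocyte, -0.98 for hypoxia angiogenesis glycolysis, 8.50 for inflammatory cytokine, 0.083 for mast basophil eosinophil, 3.37 for monocyte macrophage, 0.22 for osteoclast, -1.13 for osteoclast regulators, 4.59 for tendon ligament and 0.12 for Wnt signalling. In this model the group difference could not be separated from the muscle level of the libraries.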

Other observations

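The tests of the make-up of the muscle signal, of tendon genes, of dilution, of osteocyte against osteoblast genes and of variation within groups were chosen after the results they bear on were seen, while those of muscle isoform pairs and of other splits of the libraries were chosen before. Some gene groups not described so far also moved. Among stress and immediate early genes, the handling-sensitive transcription factor genes Fosb and Fos were higher by 3.95 and 1.85 on the log2 scale. Hsph1 (1.70) and Dusp1 (1.34) were higher too. Of the 26 tested members of the list, 15 were higher and 8 lower. That list had a median of 0.26, which turned to -0.16 with library totals and -0.39 with TPM, and passed at camera adjusted p = 0.033 but not with an estimated correlation (adjusted p = 0.29) nor under 8 of 22 alternatives (0.053 to 0.29), a number that here and for the other lists leaves out the muscle covariate. Inflammatory cytokine genes had 11 of 24 lower and 0 higher (median -0.34, camera adjusted p = 0.025, lost at adjusted p = 0.23 with an estimated correlation and under 3 of 21 alternatives, at 0.056 to 0.14), led by Nfkbia (-1.18), Socs3 (-1.30) and Lif (-2.44). Interferon response genes had 17 of 30 lower and 3 higher (median -0.37, camera adjusted p = 0.042, lost at adjusted p = 0.23 with an estimated correlation), a call also lost under 8 of 22 alternatives, from adjusted p = 0.062 without knockout-labelled replicate 1 to 0.25 among genes at FPKM 5 or more.

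Cell cycle genes had 27 of 36 higher and 0 lower with a median of 0.37 (camera adjusted p = 1.5e-06, and adjusted p = 0.022 with an estimated correlation), but the median turned and the call was lost under 5 of 22 alternatives, with library totals (-0.05, adjusted p = 0.078), limma on log2(FPKM + 1) (-0.05, 0.068) or on log2(FPKM + 0.1) (-0.05, 0.068), library weights (-0.04, 0.066) and TPM (-0.37, 0.95). Mcm3, which encodes a replication licensing factor, rose by 1.40. Among chondrocyte genes 10 of 20 tested were higher and 5 lower, and the list did not pass (median 0.75, camera adjusted p = 0.41) except with TPM (median 0.35, adjusted p = 0.024), while its median was -0.08 among genes at FPKM 5 or more. Its cartilage collagen genes Col2a1 and Col11a2 fell by 2.17 and 1.21, while Sox6, which muscle also expresses, rose by 2.45. In the senescence list, which did not pass either (camera adjusted p = 0.28, median 0.12 against a mean of -0.18, the median turning under 9 of 22 alternatives, to -0.31 with library totals, -0.54 with quantile normalization, -0.71 by limma on log2(FPKM + 1) and -1.07 with TPM), Cdkn2a, which encodes the cell cycle inhibitors p16 and p19ARF, fell from 7.54 to 0.536 FPKM (log2 fold change -3.35, SE 0.26). Endothelial, megakaryocyte and ribosomal protein lists had medians of -0.05, 0.01 and -0.07 and did not pass. With library totals the endothelial (median -0.47, camera adjusted p = 0.019) and megakaryocyte (-0.41, 0.048) lists passed in the lower direction. The ribosomal list did so under 9 of 22 alternatives, at camera adjusted p from 3.6e-11 with quantile normalization to 0.027 among genes at FPKM 5 or more, limma on log2(FPKM + 1), TPM, library totals and the fit without control replicate 1 (0.016) among them.

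Skeletal muscle and respiratory chain genes were higher in the knockout-labelled libraries. If one muscle source of unchanged fibre make-up had been added, genes expressed only in muscle would have risen by one factor. The log2 fold changes of the 28 muscle genes had an SD of 0.71. List members that other cells of the femur also express would rise by less. This spread therefore cannot decide whether that source was the whole cause. More soft tissue left on the bones may be part of the rise, since the tendon list was higher as well. Its median was 1.31, with 7 of 9 genes higher. Its call was lost with an estimated correlation (camera adjusted p = 0.11) and among genes at FPKM 5 or more (camera adjusted p = 0.22). The muscle-enriched member rose more in 5 of 5 gene pairs (median log2 difference 2.66, with Cox6a2 at 2.15 against Cox6a1 at -0.52). Of the ubiquitous members, Cox8a (-0.39), Ckmt1 (-0.97) and Slc25a5 (-0.72) also had log2 fold changes below that of the median gene, while Cox7a2 rose (0.88). The rise was thus not common to both members of every pair. The muscle-enriched members are themselves muscle genes and would rise with any gain of muscle. Among the ubiquitous members only Cox7a2 belongs to the list of 35 nuclear respiratory chain genes. The pairs therefore do not show where the rise of those 35 genes came from. An effect of the deletion or of tamoxifen on muscle or fat stays open and untested, since both go with the group.

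Osteoblast and osteoclast genes were lower in the knockout-labelled libraries. Dilution by muscle RNA would lower all other lists alike on library totals. The erythroid list had a median log2 fold change of 0.99 there and the osteoblast list -2.03. A rise of the erythroid list shows only that another source rose too, so it cannot measure dilution of bone cells. The B cell list also rose (0.51). Lists that fell did so unequally, at -0.41 for megakaryocyte, -0.47 for endothelial and -1.34 for granulocyte genes. These unequal falls argue against dilution as the whole cause of the osteoblast fall. For a smaller share of bone-forming cells and osteocytes alike, the osteocyte list was set against the osteoblast list. Its median lay 1.32 higher (permutation test over genes, p = 1e-04, two-sided, 100000 resamples, though genes are not independent). The osteocyte list also holds genes not restricted to osteocytes, such as Hyou1, also fixed in a list of unfolded protein genes. The gap therefore cannot decide this, and the osteocyte genes Sost (0.95) and Dmp1 (-0.70) went opposite ways. A change in bone cells after the deletion, an effect of tamoxifen or a different part of the bone sampled may each account for the fall beyond dilution. So may a different state of the animals, such as age, ovary status or fracture. None of these was tested.

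The libraries of a group were nearly identical, although the design text describes 3 mice per group. The amount of attached muscle would be expected to vary between dissected bones, yet the SD of the muscle list's mean level within a group lay at percentiles 4.7 and 2.31 of 10000 random lists matched on expression, in the knockout-labelled and control groups. Other lists were not low in the same way, at 62.8 and 91.8 for adipocyte, 75.6 and 87.4 for granulocyte, 93.0 and 43.2 for osteoclast, 68.0 and 48.2 for osteoblast, 20.03 and 88.58 for erythroid, 48.4 and 6.61 for B cell and 100 and 32.9 for mitochondrially encoded genes. The muscle list's mean level ranged over only 0.0060 in the knockout-labelled and 0.011 in the control group on the log2 scale. No spread for separately dissected femora was available to set beside these ranges. A rank among random lists cannot tell a pool from separate animals either. Both one pool of RNA per group and separately prepared animals of even composition therefore stay open. If each group were one pool, the p-values here would carry no information on variation between animals.

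Of the 10 splits of the 6 libraries into groups of 3, 1 gave as many genes as the real one (11732), 1 as many transcripts (8643) and 1 as many lists (22), and in each case that was the real split. The highest of the other 9 splits called 0 genes by edgeR (119 to 163 at an unadjusted p under 0.05), 1 transcript and 18 lists. Each group of those splits holds libraries of both labels, so the difference between labels enters their spread and few genes could pass. Their 0 genes therefore does not show that the real count exceeds chance. With 10 splits the share cannot fall under 0.05. The other splits still set unequal numbers of knockout-labelled libraries against each other, and they called 11 to 18 lists with the preset correlation.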
